A study of Mus musculus with 28 samples.

How the data were processed

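The deposited table holds 1 log2 expression value per probe set and array, 45101 probe sets on 28 arrays of biotin-labelled RNA. The labels name spleen as the source and their protocols speak of splenocytes. The submitters' processing notes name GCRMA and limma, with no versions or roles. That the deposited values are on a log2 scale was read from their range and from a lowest value shared by every array of an experiment, as GCRMA gives. This lowest value differs between the 2 experiments, so they were taken as normalised separately, and no level is compared between them. The scanner files were not used here, and the array's background could not be recomputed. A sample's group was taken from its labels for diet, genotype and challenge, and its experiment from its title. Null mice are floxed with MMTV-Cre and wild-type mice are floxed without it, per the labels. No pair of arrays held identical values (0 pairs).

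Probe sets were named through GEO's platform annotation: 34945 named 1 gene, 932 several and 9224 none, including 64 control probe sets. Those naming several or none were left out. Of the rest, 34741 had an Entrez identifier in the RefSeq gene table, and no symbol changed through it. Each of the 18193 genes was represented by its probe set with the highest mean, and 9010 genes had more than 1. Among 1440 genes called for LPS in wild-type control diet mice that had several tested probe sets, 8 had a probe set with the opposite sign at an unadjusted p under 0.05. In null control diet mice 13 of 367 such genes did. A gene was tested if it exceeded the 40th percentile of its array on as many arrays as the smallest condition of the fit holds. Because about that share of values is the lowest value, this filter removes little beyond genes that never leave it.

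Contrasts were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes) with Benjamini-Hochberg adjustment at 0.05. Wild-type comparisons used 20 arrays with experiment as a term (13457 genes, 15 residual degrees of freedom), and comparisons with null mice used the 16 arrays of the experiment with both genotypes (13378 genes, 8 residual degrees of freedom). The prior degrees of freedom estimated by limma were 0.772 and 0.980, so the spread of each gene was shrunk little, and genes that repeat 1 value on many arrays can pass with small changes. A value is called near the lowest where it lies within 0.5 log2 units of it. The ± after a change is the standard error from limma and the ± after a level is the SD.

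The 26 gene lists, 13 of pathways and 13 of cell types or tissues, held 486 entries, of which 438 had a probe set naming that gene alone. Of 16 pancreas genes with a probe set, 6 were tested in the 20-array fit and 15 in the 16-array fit. Lists were tested with camera at a preset correlation of 0.01, and again with the estimated correlation, adjusted over 286 tests. The median, the mean and the test differed in sign for 3 to 7 lists of a comparison, none of them called. List means per array were compared by exact two-sided permutation within experiments or conditions, adjusted over 208 tests. In the null comparisons of 2 against 2 arrays the smallest exact p is 0.333, so such a test cannot pass there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

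Genes are named by a rule fixed before the data were examined. It takes the 6 that rose and the 6 that fell most past the threshold with the same direction in both experiments, or, in 16-array fits other than interactions, without overlap between the arrays compared. Immunoglobulin, T cell receptor and clone names are left out of these. It adds up to 2 rising and 2 falling members of each list by adjusted p, Pparg and Lancl2 always, Tnf, Il1b and Il6 in the LPS and ABA contrasts of wild-type mice, and the 3 smallest p-values where fewer than 3 passed. Adipoq, Cpa1, Xist, Ifng, S1pr5, Rasd1, Wbp1, Sergef and Faf2 were chosen after their values were seen, as were the other transcripts drawn per array beside Xist, Cpa1 and Adipoq. Not every gene the rule takes is printed.

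The fits were tested on simulated data with 100 genes changed by 1 and 100 by 2 log2 units. For LPS on the control diet in wild-type mice, 61% and 91% were recovered with 7 unchanged genes called of 15116. For ABA with LPS in wild-type mice it was 66% and 96%, for ABA without LPS 42% and 83%, and for genotype 51% and 87%. For ABA with LPS in null mice it was 11% and 52%, and for the interaction of diet and genotype 3% and 25%. The changed genes had mean log2 values over 5, so recovery near the lowest value was not tested. In a simulated list test the changed list was called and 0 of the others. All simulations drew genes independently, so they do not show how often correlated members lead to a false list call.

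Alternatives fixed beforehand were quantile normalisation, median centring, no filter or a 60th percentile filter, the mean of all probe sets, trended and robust variances, array weights, 1 fit of all arrays, replicate number as a block, each experiment alone, no experiment term, a fold change over 1.5, and each array left out. A high-Xist term, leaving out the 4 arrays with Cpa1 over 2 log2 units above the lowest value, the erythroid list mean as a covariate, the permutation of list means and a test of the difference between experiments were chosen after seeing the data. The erythroid list mean itself fell with LPS in wild-type mice, so fits with it as a covariate do not give the full LPS change.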

Results

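Spleen RNA from 28 samples was measured on a 1-colour mouse expression array with 45101 probe sets. Mice ate a control diet or a diet with abscisic acid (ABA), a plant hormone, and were or were not challenged with lipopolysaccharide (LPS), the bacterial membrane component sensed by TLR4. The wild-type-only experiment had 4 arrays for each diet with LPS and 2 for each diet without. The other experiment held wild-type and PPARg-null mice (floxed Pparg with and, for the null mice, MMTV-Cre), with 2 arrays in each of 8 groups. Values are the authors' log2 GCRMA values, in which the lowest value, 2.29 in the wild-type-only experiment and 2.24 in the other, was shared by 35.9% to 41.9% of an array's probe sets. Arrays correlated at 0.942 or more within an experiment and at 0.769 to 0.837 between experiments, so every comparison was made within experiments. The number of arrays limits the precision. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples.

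Pparg, the targeted gene and a nuclear receptor of lipid metabolism, has 1 probe set, with low values in both genotypes. In the experiment with both genotypes it read 2.60 ± 0.12 in wild-type and 2.90 ± 0.56 in null mice on the control diet without LPS, and 2.38 ± 0.09 and 2.45 ± 0.00 with LPS (SD, n = 2 each). On the ABA diet it read 3.00 ± 0.79 and 2.88 ± 0.61 without LPS, and 2.38 ± 0.09 and 2.45 ± 0.00 with LPS (SD, n = 2 each). In the wild-type-only experiment it read 2.29 ± 0.00 with LPS on either diet (SD, n = 4 each), and 2.58 ± 0.41 on the control diet and 3.02 ± 0.95 on the ABA diet without LPS (SD, n = 2 each). The probe set's place relative to the deleted part is not given in the sources used here, so it does not check the genotype labels. Lancl2, known as a receptor for ABA, read 7.57 ± 0.50 in wild-type and 8.07 ± 0.67 in null mice on the control diet without LPS (SD, n = 2 each).

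Sex is not in the labels. Xist, expressed from the inactive X chromosome, was high (10.4 to 12.6) on all 12 arrays of the wild-type-only experiment, and high on 6 and at most 2.25 on 10 arrays of the other. There, both wild-type arrays with LPS on the control diet had high Xist, while both with LPS on the ABA diet, both without LPS on the control diet and both null arrays without LPS on the control diet had low Xist. Cpa1, a pancreatic digestive enzyme, lay over 2 log2 units above the lowest value on 4 arrays. These were 1 wild-type array on the control diet without LPS and 1 with LPS in the wild-type-only experiment, and 1 null array without LPS on each diet.

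**Figure D1:**
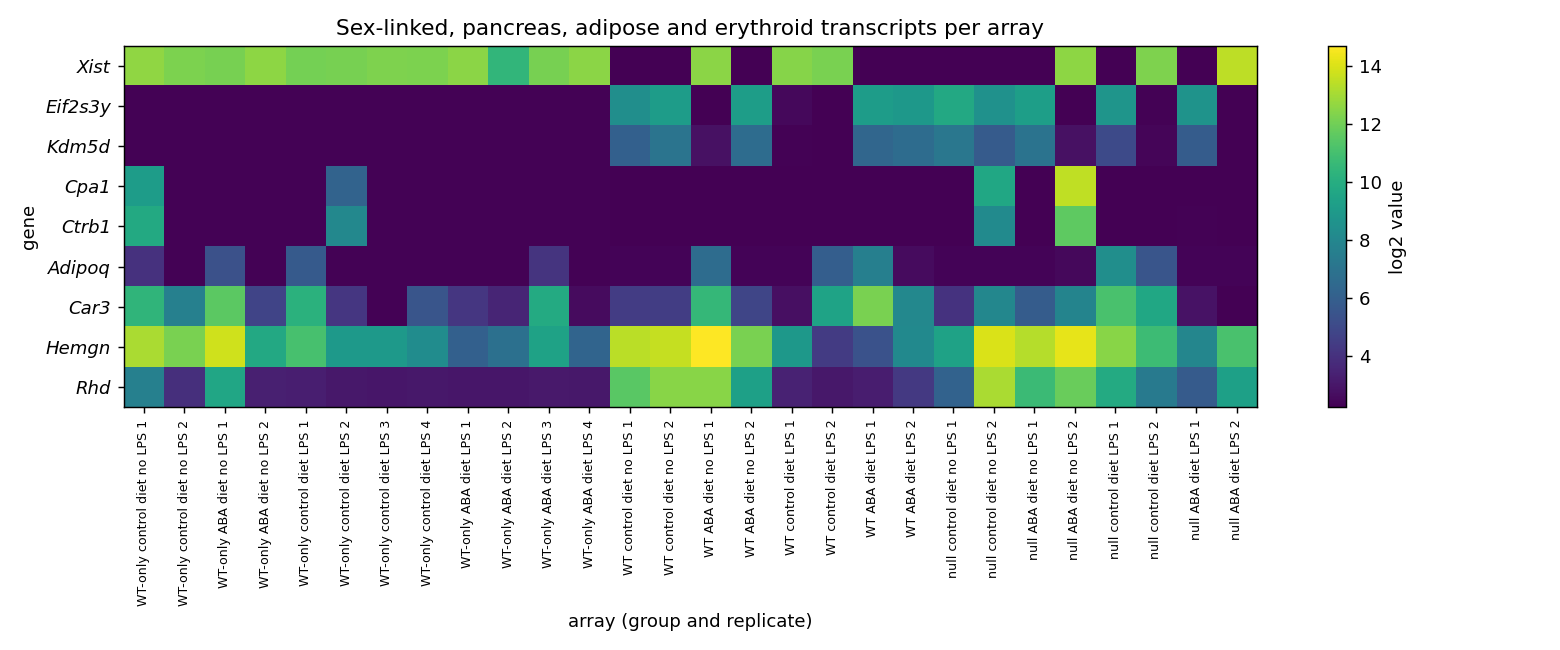
Log2 values (colour) of 9 sex-linked, pancreas, adipose and erythroid transcripts (vertical axis) on the 28 arrays (horizontal axis, named by group and replicate). Xist is high on all 12 arrays of the wild-type-only experiment and on 6 of the 16 others, and Cpa1 stands out on 4 arrays.

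LPS changed the wild-type spleen strongly on the control diet. Acod1, which makes the antimicrobial metabolite itaconate, rose by 8.49 ± 0.21 log2 units (SE), from 2.34 ± 0.07 (SD, n = 2) to 10.88 ± 0.20 (SD, n = 4) in the wild-type-only experiment. Il1rn, the interleukin-1 receptor antagonist, rose by 8.17 ± 0.28 and Saa3, an acute phase protein, by 8.29 ± 0.49. Mmp13, a collagenase, rose by 7.98, Gzmb, a cytotoxic granule protease, by 7.51, and Ubd, a ubiquitin-like protein, by 6.77. Slc40a1, the iron exporter ferroportin, fell by 5.37 ± 0.46 and Cd163, the haemoglobin scavenger receptor of macrophages, by 6.15 ± 0.55. Cd163 lay near the lowest value on all 6 arrays with LPS. Without LPS Mmp13 did on 4 of 4, Acod1 on 2 of 4 and Il1rn on 1 of 4. The sizes of these changes depend on that value. In all, 1428 genes rose and 1009 fell of 13457 tested (limma, Benjamini-Hochberg adjusted p under 0.05), and 98.8% of them had the same direction in both experiments. These genes were called in a fit of both experiments, which favours a shared direction. Of 9466 tested genes that changed by over 0.01 log2 units in each experiment, 76.0% had the same direction. With quantile normalisation 1196 rose and 1289 fell, and with arrays centred on their medians 1687 and 888.

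Of the 26 lists fixed beforehand, camera called 13 in this comparison, and the 2 given first held with an estimated correlation. Type I interferon-stimulated genes had the highest median, 3.92: 22 of 24 members rose and 0 fell, and 22 passed when adjusted over the list alone (camera adjusted p = 6.54e-30, and adjusted p = 0.00309 with an estimated correlation). Zbp1, a nucleic acid sensor, rose by 5.49 and Mx1, an antiviral GTPase, by 5.21. Of 25 inflammatory cytokines and chemokines, 15 rose (16 adjusted over the list alone), among them the neutrophil attractant Cxcl2 by 6.04, Il6 by 3.85 and Il1b by 3.18 (camera adjusted p = 1.27e-12, and adjusted p = 0.0350 with an estimated correlation). Il6 lay near the lowest value on 4 and Cxcl2 on 2 of the 4 arrays without LPS, so the sizes of their changes depend on that value. Tnf read 1.09 ± 0.48 higher and did not pass (adjusted p = 0.133), and lay near the lowest value on 8 of 10 arrays. Of 19 interferon-gamma-induced genes, 18 rose (18 adjusted over the list alone), with Gbp2, a guanylate-binding protein, at 5.73 and Irgm1 at 3.81 (camera adjusted p = 3.68e-23, adjusted p = 0.0811 with an estimated correlation). Of 14 acute phase and antimicrobial genes, 10 rose (10 adjusted over the list alone), including Sod2, the mitochondrial superoxide dismutase, by 3.34 (camera adjusted p = 1.99e-12, adjusted p = 0.0811 with an estimated correlation). Of 24 TLR4 and NF-kB genes, 14 rose (15 adjusted over the list alone), with the feedback inhibitors Socs3 at 3.66 and Tnfaip3 at 3.17 (camera adjusted p = 6.56e-09, adjusted p = 0.429 with an estimated correlation).

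Dusp1, a phosphatase that damps MAP kinases, rose by 2.95 and Jun by 2.28 among 17 immediate-early and cAMP-responsive genes, of which 6 rose and 1, Btg2, fell (8 adjusted over the list alone; camera adjusted p = 0.00157, adjusted p = 0.731 with an estimated correlation). Of 12 glucocorticoid-responsive genes 5 rose (6 adjusted over the list alone), among them the decoy receptor Il1r2 by 4.19 (camera adjusted p = 0.00336, adjusted p = 0.731 with an estimated correlation). Genes of antigen presentation went both ways: the co-stimulatory Cd40 rose by 2.90 and Cd86 by 2.81, while the class II genes H2-Ob and H2-Ab1 fell by 2.69 and 1.01. In that list of 13, 3 rose and 4 fell (8 adjusted over the list alone; median -0.46, camera adjusted p = 0.571). Atf3 rose by 3.32 and the chaperone Hspa5 by 0.65 among 20 endoplasmic reticulum stress genes (2 rose, 2 adjusted over the list alone; camera adjusted p = 0.379). Of 17 cholesterol synthesis genes Pmvk rose by 0.51 and Stard4, a sterol carrier, fell by 1.29 (2 adjusted over the list alone; camera adjusted p = 0.987). Of 36 oxidative phosphorylation genes only Cycs, cytochrome c, rose, by 0.72 (0 adjusted over the list alone; camera adjusted p = 0.455).

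Several erythroid, cell cycle, B cell, T cell and macrophage genes fell after LPS. Of 15 erythroid genes 7 fell (12 adjusted over the list alone), including the anion exchanger Slc4a1 by 5.30 ± 1.12 and the membrane protein Epb42 by 4.38 ± 0.98 (median -2.32, camera adjusted p = 3.9e-05, adjusted p = 0.892 with an estimated correlation). Epb42 lay near the lowest value on 4 of 6 arrays with LPS, so the size of its change depends on that value. Rhd, a blood group antigen, fell by 5.34, and Hemgn, a nuclear protein of erythroid precursors, by 4.70. Of 27 cell cycle genes 5 fell (6 adjusted over the list alone), with Mki67 at -2.62 and Ccnb2 at -2.69 (camera adjusted p = 0.000125, adjusted p = 0.976 with an estimated correlation). With the erythroid covariate, chosen after seeing the data, the median of this list turned from -1.14 to 0.42. The covariate itself fell with LPS, so it also takes out any LPS change that the 2 lists share. B cell genes fell in 5 of 12 cases (5 adjusted over the list alone), such as Fcer2a, the low-affinity IgE receptor, by 2.52 (camera adjusted p = 0.00353, adjusted p = 0.938 with an estimated correlation). T cell genes fell in 2 of 14 cases (2 adjusted over the list alone), such as Thy1 by 2.43 (camera adjusted p = 0.0183, adjusted p = 0.976 with an estimated correlation). Of 16 macrophage genes 5 fell and 1 rose, the scavenger receptor Marco by 1.52 (8 adjusted over the list alone; camera adjusted p = 0.0126, adjusted p = 0.976 with an estimated correlation). Among 11 natural killer and cytotoxic genes 3 rose and 1, the receptor Klrd1, fell by 1.46 (7 adjusted over the list alone; camera adjusted p = 0.00360, adjusted p = 0.697 with an estimated correlation).

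The other lists were not called. Among 22 PPARg and lipid genes, Plin2, a lipid droplet coat protein, rose by 1.73 and Pdk4, a brake on glucose oxidation, by 2.75, while the lipase Mgll fell by 2.25 and the thiolase Acaa2 by 1.38 (2 rose, 4 fell, 7 adjusted over the list alone; median 0.08, mean -0.04, camera direction down, adjusted p = 0.907). Of 10 dendritic cell genes 3 rose and 3 fell (7 adjusted over the list alone), among them Bst2 at 3.27, Ly75 at 2.16 and Itgax at -2.13 (median -0.07, mean 0.42, camera direction up, adjusted p = 0.731). Prdm1, a regulator of plasma cells, rose by 1.80, as the only one of 9 plasma cell genes (1 adjusted over the list alone; median -0.26, mean 0.01, camera direction down, adjusted p = 0.851). Of 13 endothelial and stromal genes the collagen Col4a1 rose by 2.39 and Cdh5 by 1.39, while Tek, near the lowest value on 4 of 6 arrays with LPS, fell by 1.34 (4 adjusted over the list alone; camera adjusted p = 0.834). None passed among 15 neutrophil genes (median 0.12, mean 0.02, camera direction down, adjusted p = 0.987), 9 of megakaryocytes and platelets (-0.19, camera adjusted p = 0.447), 6 of pancreas (-1.36, camera adjusted p = 0.136) and 5 of liver (0.03, camera adjusted p = 0.947), or when adjusted over the list alone (0 in each). The same held for 8 adipose genes (median 0.01, mean 0.00, camera direction down, adjusted p = 0.844). Within the wild-type-only experiment and the other, 1686 and 916 genes passed, with Xist differing between the groups of the latter, and 585 passed without the experiment term. With alternatives chosen after seeing the data, 1594 passed with a term for high Xist and 1504 with the erythroid list mean as covariate.

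On the ABA diet LPS raised Acod1 by 7.66 ± 0.21, Il1rn by 7.87 ± 0.28, Saa3 by 7.61 and Cxcl2 by 6.54. Cd163 fell by 6.01 ± 0.55, Slc40a1 by 5.56 and Apol11b, an apolipoprotein L family member, by 5.12. Cd163 lay near the lowest value on 5 of 6 arrays with LPS. Without LPS Cxcl2 did on 3 of 4, Acod1 on 2 of 4 and Il1rn on 1 of 4. The sizes of these changes depend on that value. In all 1202 genes rose and 852 fell, against 1050 and 1075 with quantile normalisation. Of the 1202 and 852, 890 rose and 496 fell on the control diet as well, against 128 and 63.9 for independent lists, and log2 changes on the 2 diets correlated at 0.91 across genes, which are not independent replicates. Camera called 11 lists, of which 1 held with an estimated correlation: type I interferon genes rose in 22 of 24 cases (22 adjusted over the list alone; median 3.50, camera adjusted p = 6.54e-30, and adjusted p = 0.00309 with an estimated correlation). Cytokines rose in 14 of 25 cases (16 adjusted over the list alone; adjusted p = 0.0583 with an estimated correlation), and interferon-gamma-induced genes in 18 of 19 (18 adjusted over the list alone; adjusted p = 0.0811 with an estimated correlation). Acute phase genes rose in 11 of 14 cases (12 adjusted over the list alone; adjusted p = 0.0613 with an estimated correlation) and TLR4 and NF-kB genes in 13 of 24 (18 adjusted over the list alone; adjusted p = 0.399 with an estimated correlation). Glucocorticoid-responsive genes rose in 9 of 12 cases (9 adjusted over the list alone), led by Il1r2 at 5.48 and Errfi1 at 3.66 (camera adjusted p = 8.22e-07, adjusted p = 0.166 with an estimated correlation). Cell cycle genes fell in 15 of 27 cases (25 adjusted over the list alone; adjusted p = 0.862 with an estimated correlation) and erythroid genes in 8 of 15 (14 adjusted over the list alone; adjusted p = 0.748 with an estimated correlation). Cd36, a fatty acid transporter under PPARg control, fell by 1.74 and Pparg, near the lowest value on 8 of 10 arrays, by 0.68 ± 0.22 (limma, adjusted p = 0.0430). The fall of Pparg rests on 1 array without LPS in each experiment. Without LPS Pparg read 3.70 and 2.35 in the wild-type-only experiment and 2.45 and 3.56 in the other, against 2.29 to 2.45 with LPS. Within the wild-type-only experiment 1931 genes passed and within the other 439, and 1369 passed without ABA diet no LPS replicate 1 of the former. There were 517 without the experiment term, 1211 with array weights and 865 with the erythroid covariate.

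**Figure D2:**
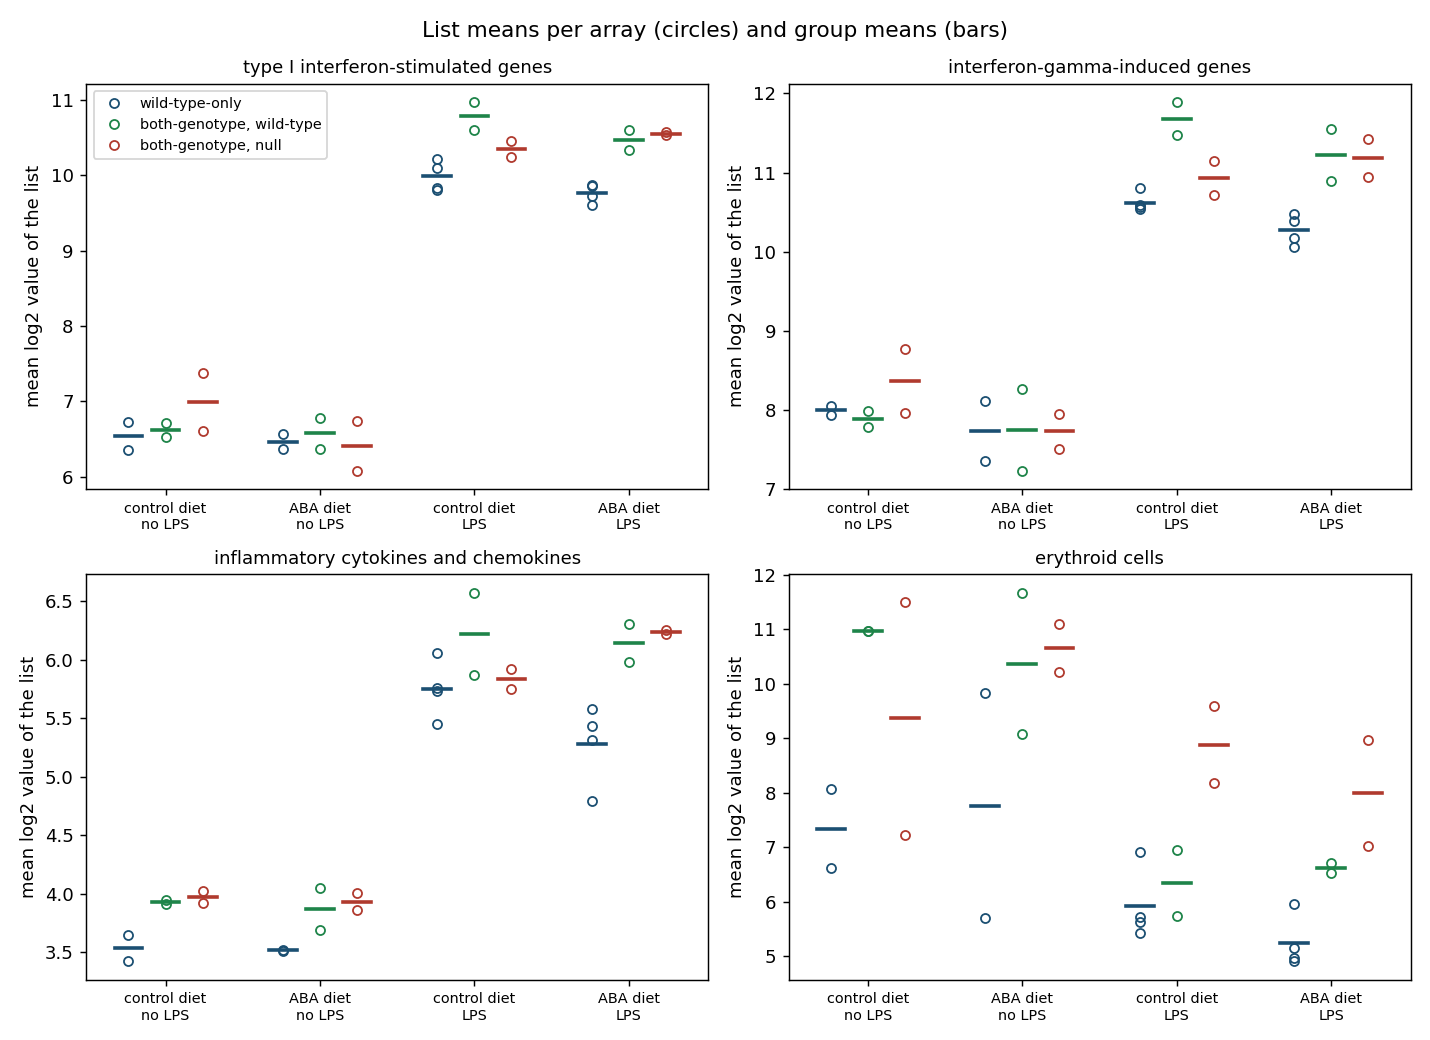
Mean log2 value of 4 gene lists (vertical axes) on each array (circles) with group means (bars), by diet and LPS, for the wild-type-only experiment (blue) and the wild-type (green) and null (red) mice of the other. Type I interferon list means lie between 9.61 and 10.97 with LPS and at or below 7.38 without, while erythroid means spread widely within groups.

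The 2 diets were compared in 12 wild-type arrays with LPS. This gives the difference between diets with LPS, while a change of the LPS response itself is the interaction of diet and LPS given below. In all, 2 genes passed and both fell on the ABA diet: BC023105 by 1.37 ± 0.17, from 5.65 ± 0.26 to 4.25 ± 0.09 (SD, n = 4 each) in the wild-type-only experiment, and Qsox2, a disulfide-forming oxidase, by 0.96 ± 0.13 (adjusted p = 0.00727 for both, limma). The third smallest p belonged to Cnih1, which read -0.45 ± 0.09 without passing. At an unadjusted p under 0.05 there were 684 genes, against 673 expected by chance. Interferon-gamma-induced genes had a median of -0.40 (19 members, 0 passed, 0 adjusted over the list alone), with -0.42 and -0.35 in the 2 experiments (camera adjusted p = 2.15e-05, adjusted p = 0.874 with an estimated correlation). The difference of their array means was tested by exact permutation within experiments (two-sided p = 0.0143 over 420 arrangements, adjusted p = 0.129). Neutrophil genes had a median of 0.61 (0 of 15 passed, 0 adjusted over the list alone; camera adjusted p = 0.000261, adjusted p = 0.874 with an estimated correlation), and natural killer and cytotoxic genes -0.42 (0 of 11 passed, 1 adjusted over the list alone; camera adjusted p = 0.00670, adjusted p = 0.741 with an estimated correlation). Cytokine genes had a median of -0.21 (0 of 25 passed, 0 adjusted over the list alone), with -0.52 in the wild-type-only experiment and 0.01 in the other (camera adjusted p = 0.0111, adjusted p = 0.746 with an estimated correlation). Camera called 8 lists in all, and with an estimated correlation their adjusted p lay between 0.741 and 0.999. Il6 read -1.37 ± 0.70, Il1b -0.31 ± 0.59 and Tnf -0.21 ± 0.43, and none of them passed. Both calls were lost with the replicate number as a block and with a term for high Xist, chosen after seeing the data, and 78 genes passed with array weights. Log2 changes of the 2 experiments correlated at -0.05 across genes, with 13 genes past the threshold in the wild-type-only experiment and 31 in the other. In the other experiment both control diet arrays with LPS had high Xist and both ABA diet arrays low Xist. Diet and sex cannot be told apart there, so the correlation does not show whether an ABA effect was repeated.

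**Figure D3:**
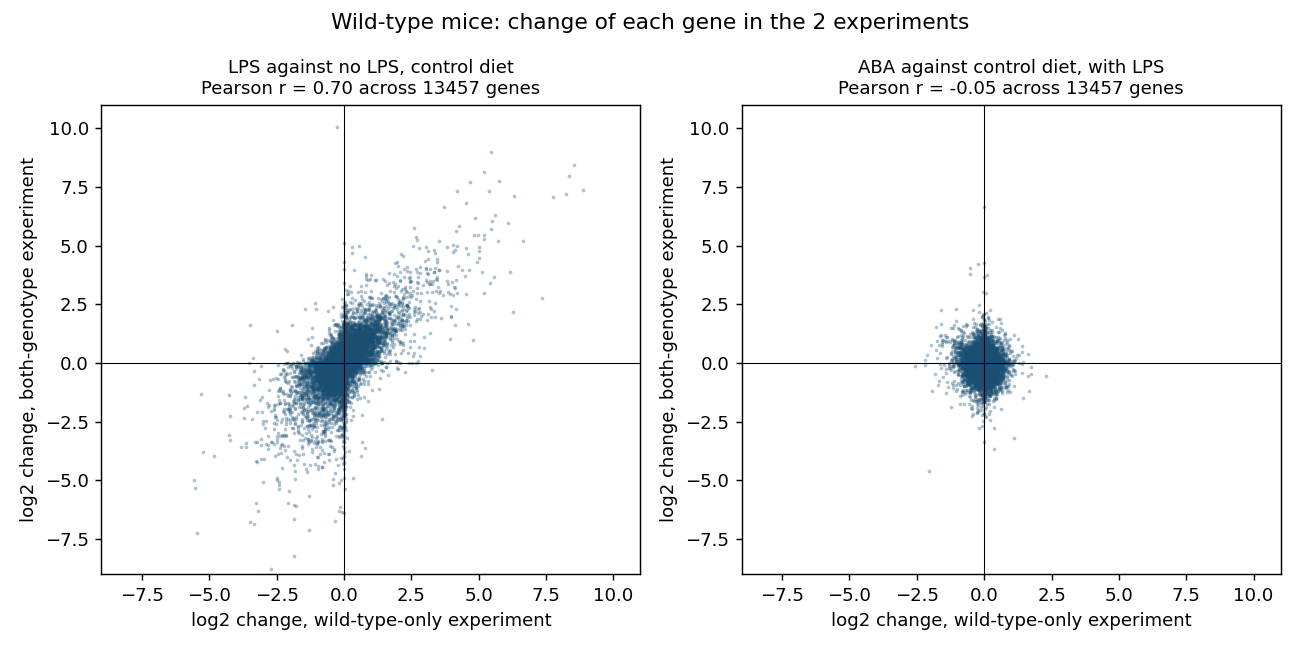
Log2 change of 13457 genes in wild-type mice in the wild-type-only experiment (x axis) and the experiment with both genotypes (y axis), 1 point per gene, for LPS on the control diet (left) and for ABA with LPS (right). The LPS changes correlate at 0.70 and the ABA changes at -0.05. In the experiment with both genotypes the groups compared in either panel also differed in Xist, so sex could enter the y axis.

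Without LPS, ABA changed 1 gene in wild-type mice: Thap11, a transcription factor, fell by 0.95 ± 0.13, from 6.45 ± 0.04 to 5.53 ± 0.13 (SD, n = 2 each) in the wild-type-only experiment (adjusted p = 0.0162, limma). Lrrc45 read -0.83 ± 0.16 and Odr4 -0.43 ± 0.08 without passing. At an unadjusted p under 0.05 there were 788 genes. B cell genes had a median of -0.42 (0 of 12 passed, 0 adjusted over the list alone; camera adjusted p = 0.00387, adjusted p = 0.941 with an estimated correlation) and T cell genes -0.30 (0 of 14 passed, 0 adjusted over the list alone; camera adjusted p = 0.00670, adjusted p = 0.976 with an estimated correlation). Glucocorticoid-responsive genes had a median of -0.44 (0 of 12 passed, 0 adjusted over the list alone; camera adjusted p = 0.00953, adjusted p = 0.765 with an estimated correlation). The 6 pancreas genes tested had -1.28 (0 adjusted over the list alone; camera adjusted p = 0.0204, adjusted p = 0.976 with an estimated correlation), and 1 of the control diet arrays had high Cpa1. No gene passed with quantile normalisation, arrays centred on their medians, array weights, 1 fit of all 28 arrays, the replicate number as a block or no experiment term. The same held without wild-type control diet no LPS replicate 1 or 2 of the experiment with both genotypes. The count was 2 and 4 without replicates 1 and 2 of the control diet group and 5 and 6 without those of the ABA group in the wild-type-only experiment. It was 6 and 5 without ABA replicates 1 and 2 of the other. Within the 2 experiments 62 and 0 genes passed.

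No gene passed for an interaction of diet and LPS in wild-type mice (limma, 561 genes at an unadjusted p under 0.05 and 673 expected). Ppcdc, an enzyme of coenzyme A synthesis, read 1.44 ± 0.25, BC023105 -1.36 ± 0.27 and Lrrc45 1.01 ± 0.20, the smallest p-values, with adjusted p from 0.382 to 0.674. Glucocorticoid-responsive genes had a median of 0.52 (0 of 12 passed, 1 adjusted over the list alone; camera adjusted p = 0.000374, adjusted p = 0.514 with an estimated correlation). B cell genes had 0.63 (0 of 12 passed, 0 adjusted over the list alone; camera adjusted p = 0.000408, adjusted p = 0.862 with an estimated correlation) and cell cycle genes -0.66 (0 of 27 passed, 0 adjusted over the list alone; camera adjusted p = 0.000291, adjusted p = 0.981 with an estimated correlation). The wild-type-only experiment alone gave 37 genes and the other 1. In the former, 1 gene passed without control diet no LPS replicate 1, 3 without replicate 2 and 1 without ABA diet no LPS replicate 1, and in the other 1 without wild-type ABA diet no LPS replicate 1.

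Averaged over the 4 conditions, null and wild-type spleens differed in 1 of 13378 genes. Il2ra, the interleukin-2 receptor alpha chain, fell by 0.60 ± 0.06 in null mice (adjusted p = 0.0330, limma), and was near the lowest value on 14 of 16 arrays. It read 4.49 ± 0.29 in wild-type mice with LPS on the control diet and 2.30 ± 0.06 in null mice of that condition (SD, n = 2 each). Pparg read 0.08 ± 0.20 and Lancl2 0.23 ± 0.38 higher in null mice, and neither passed. At an unadjusted p under 0.05 there were 273 genes against 669 expected. No gene passed with quantile normalisation, arrays centred on their medians, the 60th percentile filter, the mean of all probe sets, array weights or the replicate number as a block, or with a high-Xist term or the erythroid covariate, both chosen after seeing the data. Il2ra did not pass in 1 fit of all 28 arrays, where 12 other genes did. Erythroid genes had a median of 0.80 (0 of 14 passed, 0 adjusted over the list alone; camera adjusted p = 0.00157, adjusted p = 0.976 with an estimated correlation), and 0.11 with the test's direction turned without the arrays with high Cpa1. Pancreas genes had 1.78 (0 of 15 passed, 0 adjusted over the list alone; camera adjusted p = 1.24e-07, adjusted p = 0.892 with an estimated correlation), and 0.00 without the arrays with high Cpa1. Without those arrays, an alternative chosen after seeing the data, 100 genes passed. Leaving out 1 array gave 0 genes for null ABA diet no LPS replicate 2 and null ABA diet LPS replicates 1 and 2, and 67 for null control diet no LPS replicate 2. It gave 16 for replicate 1 of that group, 12 for null ABA diet no LPS replicate 1, and 2 and 18 for null control diet LPS replicates 1 and 2. It gave 4 and 21 for wild-type control diet no LPS replicates 1 and 2, 4 for wild-type ABA diet no LPS replicate 2 and 3 for wild-type ABA diet LPS replicate 2.

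LPS also changed the null spleens. On the control diet Saa3 rose by 9.52 ± 0.50, from 3.89 ± 0.38 to 13.41 ± 0.10 (SD, n = 2 each). Mmp13, near the lowest value on both arrays without LPS, rose by 9.34 ± 0.43. Il1rn rose by 7.73, Acod1 by 7.44, the chemokine Cxcl10 by 7.15 and Slfn4, an interferon-induced Schlafen gene, by 7.14. Cd163 fell by 6.64 ± 1.02, the transporter Abca9 by 4.98, Stab2, a scavenger receptor of sinusoidal endothelium, by 4.74, and Slc40a1 fell by 4.56. In all 332 genes rose and 447 fell of 13378, against 466 and 278 with quantile normalisation and 753 and 261 with arrays centred on their medians. Camera called 12 lists, and with an estimated correlation their adjusted p lay between 0.0583 and 0.999. Type I interferon genes rose in 17 of 24 cases (22 adjusted over the list alone; median 3.27, adjusted p = 0.0583 with an estimated correlation), with Zbp1 at 5.44 and Oasl1 at 5.24. Acute phase genes rose in 9 of 14 (11 adjusted over the list alone), with the siderophore-binding Lcn2 at 5.97 (adjusted p = 0.0583 with an estimated correlation), interferon-gamma-induced genes in 12 of 20 (14 adjusted over the list alone; adjusted p = 0.410 with an estimated correlation) and cytokines in 7 of 25 (9 adjusted over the list alone; adjusted p = 0.0811 with an estimated correlation). Chil3, a chitinase-like protein, rose by 2.92, as 1 of 15 neutrophil genes (3 adjusted over the list alone; median 1.24, adjusted p = 0.697 with an estimated correlation). Of the adipose genes Thrsp, a lipogenic regulator, rose by 2.35 (1 of 8 rose, 2 adjusted over the list alone; adjusted p = 0.746 with an estimated correlation). Fat in some arrays was not tested as a source of the adipose values. In the same fit 655 genes rose and 261 fell in wild-type mice, sharing 190 and 130 with null mice against 16.3 and 8.72 for independent lists. The count was 340 without null control diet LPS replicate 1 and 1323 without null control diet no LPS replicate 2, 214 with array weights and 1924 in 1 fit of all 28 arrays. With alternatives chosen after seeing the data it was 1181 without the 4 arrays with high Cpa1, 485 with a high-Xist term and 1783 with the erythroid covariate.

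The LPS change on the control diet differed between genotypes for 42 genes, 24 more positive and 18 more negative in null mice. H1f7, a testis-type linker histone, differed by 2.91 ± 0.12 (adjusted p = 2.36e-05, limma), reading 2.29 ± 0.07 and 4.53 ± 0.15 in null mice without and with LPS and 3.79 ± 0.03 and 3.12 ± 0.02 in wild-type mice (SD, n = 2 each). Both null arrays without LPS lay near the lowest value, so the size of this difference and its SE depend on that value. Bpifb1, a secreted protein of airway epithelium, differed by 4.19 ± 0.40 and Zbtb3, a zinc finger protein, by 4.15 ± 0.47, while Rab19 differed by -2.54, the kinase Pim2 by -2.23 and Il2ra by -2.17. Of these groups, Il2ra lay above the range near the lowest value only in wild-type mice with LPS, so the size of its difference depends on that value. Both wild-type arrays with LPS on the control diet had high Xist and both without LPS low Xist, so sex could enter these differences. The median of all genes was itself shifted by -0.20. With arrays centred on their medians, 15 genes were more positive and 2 more negative, and 15 of these 17 were among the 42. H1f7 then differed by 3.21, Bpifb1 by 4.48, Zbtb3 by 4.45, Rab19 by -2.25 and Il2ra by -1.87, all still past the threshold, while Pim2, at -1.94, did not pass. Quantile normalisation gave 25 more positive and 11 more negative. Erythroid genes had a median difference of 4.03 (0 of 14 passed, 0 adjusted over the list alone; camera adjusted p = 2.13e-09, adjusted p = 0.746 with an estimated correlation), as their mean went from 10.98 to 6.35 in wild-type and from 9.37 ± 3.02 to 8.88 ± 1.00 in null mice. Cell cycle genes had 1.68 (0 of 27 passed, 0 adjusted over the list alone; camera adjusted p = 1.98e-07, adjusted p = 0.976 with an estimated correlation), and -0.89 with the erythroid covariate, chosen after seeing the data. Interferon-gamma-induced genes had -1.17 (0 of 20 passed, 0 adjusted over the list alone; camera adjusted p = 0.000952, adjusted p = 0.976 with an estimated correlation). Leaving out 1 array gave 400 and 104 genes for null control diet no LPS replicates 2 and 1, 151 for null control diet LPS replicate 2, 167 for wild-type control diet no LPS replicate 2, and 77 and 19 for wild-type control diet LPS replicates 1 and 2. The 60th percentile filter left 11 genes, array weights 15, the replicate number as a block 26, the high-Xist term 25 and the erythroid covariate 10. In 1 fit of all 28 arrays 261 passed, and 366 did without the 4 arrays with high Cpa1.

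In null mice given LPS, ABA raised 8 genes and lowered 5. Ap2b1, a clathrin adaptor subunit, rose by 2.51 ± 0.32, from 6.69 ± 0.18 to 9.19 ± 0.32 (SD, n = 2 each), the Ras inhibitor Rasa4 by 2.17 ± 0.26, the histone methyltransferase Kmt2d by 1.84 and Arap3 by 1.62. H1f7 fell by 0.74 ± 0.09. Adipose genes had a median of -1.14 (0 of 8 passed, 0 adjusted over the list alone; camera adjusted p = 0.000101, adjusted p = 0.474 with an estimated correlation), and Adipoq, the fat hormone adiponectin, read 6.95 ± 2.04 on the control diet and 2.36 ± 0.00 on the ABA diet (SD, n = 2 each). TLR4 and NF-kB genes had 0.45 (0 of 24 passed, 1 adjusted over the list alone; camera adjusted p = 0.00854, adjusted p = 0.976 with an estimated correlation). None passed with arrays centred on their medians, with the 60th percentile filter, with the mean of all probe sets or with a high-Xist term (limma, 1061 at an unadjusted p under 0.05 in the fit without these). Leaving out 1 array gave 69 and 177 genes for null control diet LPS replicates 1 and 2 and 34 for null ABA diet LPS replicate 2.

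Without LPS, ABA raised 12 genes and lowered 12 in null mice, against 9 and 4 with arrays centred on their medians. Zbtb3 rose by 2.94 ± 0.34, from 2.76 ± 0.05 to 5.70 ± 0.59 (SD, n = 2 each), the amino acid transporter Slc1a4 by 2.92, Chil1, a chitinase-like protein, by 2.68 and Bpifb1 by 2.59. Zbtb3 and Bpifb1 are also named for the difference of the LPS change between genotypes. Both contrasts share the null arrays without LPS on the control diet, so these results are not independent. Susd3 fell by 2.05, the transcription factor Tfcp2 by 1.64 and Mmp2, a gelatinase, by 1.42 ± 0.10. Type I interferon genes had a median of -0.67 (0 of 24 passed, 0 adjusted over the list alone; camera adjusted p = 0.0175, adjusted p = 0.976 with an estimated correlation) and neutrophil genes 0.54 (0 of 15 passed, 0 adjusted over the list alone; camera adjusted p = 0.000491, adjusted p = 0.746 with an estimated correlation). Pancreas genes had 2.14 (0 of 15 passed, 0 adjusted over the list alone; camera adjusted p = 0.000631, adjusted p = 0.976 with an estimated correlation), with high Cpa1 on 1 array of each group. Leaving out 1 array gave 219 and 355 genes for null control diet no LPS replicates 1 and 2 and 101 and 41 for null ABA diet no LPS replicates 1 and 2, and leaving out the 4 arrays with high Cpa1 gave 266.

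The ABA effect with LPS differed between genotypes for 17 genes, 7 more positive and 10 more negative in null mice. Klhl17 differed by -3.26 ± 0.41, Bpifb1 by -3.03 ± 0.40 and the PTIP-associated Pagr1a by -2.18, while Tmtc2 differed by 2.18, the serine protease St14 by 2.17, the lipid phosphodiesterase Smpdl3b by 2.15 and Il2ra by 2.00 ± 0.16 (limma). Il2ra lay near the lowest value in all these groups but wild-type mice on the control diet, so its difference and SE depend on that value. Its fall on the ABA diet in wild-type mice was not seen in the wild-type-only experiment. There it read 7.03 to 8.74 with LPS on the ABA diet and 6.83 to 9.15 on the control diet. Zswim1 changed by -0.01 there and by -1.14 in the other, though its probe set hardly varied in the former. In wild-type mice Klhl17 read 4.99 ± 0.28 on the control diet and 7.26 ± 0.30 on the ABA diet, and in null mice 7.65 ± 0.03 and 6.65 ± 0.61 (SD, n = 2 each). Adipose genes had a median difference of -2.20 (0 of 8 passed, 3 adjusted over the list alone; camera adjusted p = 3.63e-06, adjusted p = 0.321 with an estimated correlation) and macrophage genes -0.94 (0 of 16 passed, 0 adjusted over the list alone; camera adjusted p = 0.00233, adjusted p = 0.976 with an estimated correlation). Interferon-gamma-induced genes had 0.60 (0 of 20 passed, 0 adjusted over the list alone; camera adjusted p = 0.0391, adjusted p = 0.999 with an estimated correlation). Fat in some arrays was not tested as a source of the adipose value. Both wild-type arrays with LPS on the control diet had high Xist and both on the ABA diet low Xist, so sex could enter these differences. This contrast and the difference of the LPS change between genotypes share the groups with LPS on the control diet, so the 2 sets of genes are not independent. None passed with arrays centred on their medians or with the 60th percentile filter (limma, 992 at an unadjusted p under 0.05 in the fit without these), and 2 did with a high-Xist term. Leaving out 1 array gave 31 and 129 genes for null control diet LPS replicates 1 and 2, 35 for null ABA diet LPS replicate 2, 75 and 7 for wild-type control diet LPS replicates 1 and 2, and 32 for wild-type ABA diet LPS replicate 1 or 2.

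**Figure D4:**
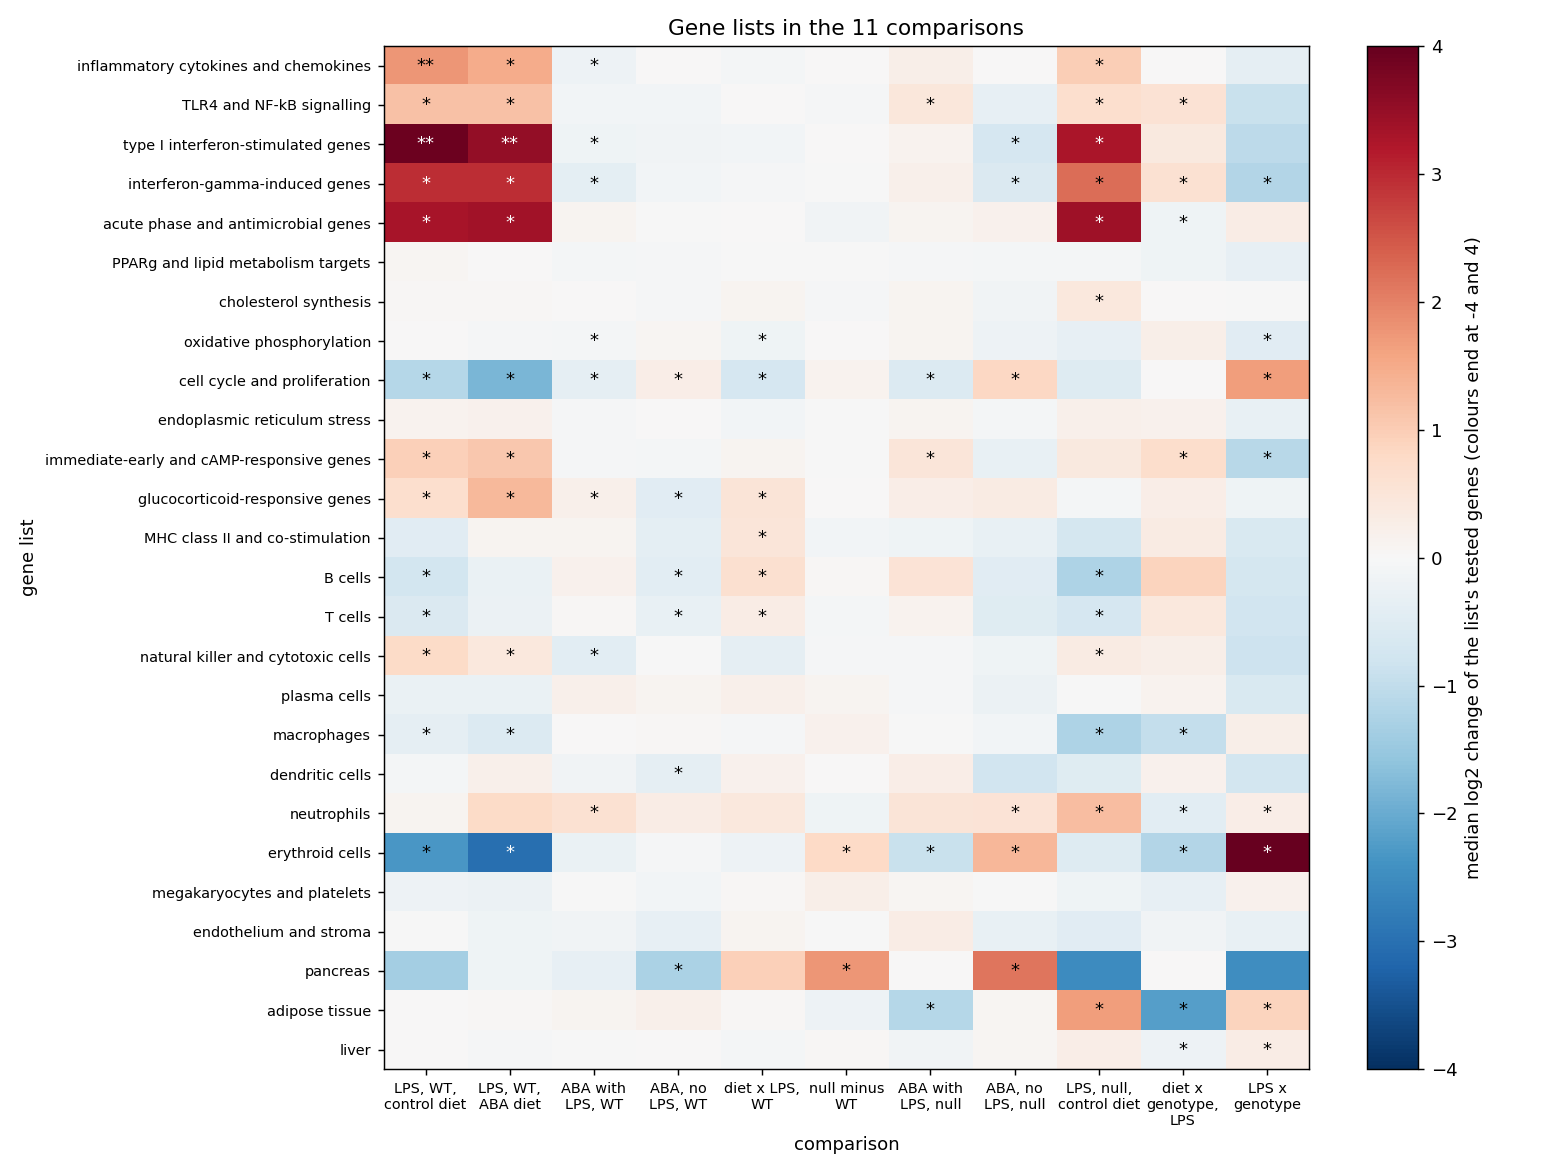
Median log2 change (colour) of the tested members of 26 gene lists (vertical axis) in the 11 comparisons (horizontal axis). A star marks a camera adjusted p under 0.05 and a double star one that holds with an estimated correlation, which are type I interferon genes with LPS on both diets and cytokines with LPS on the control diet, all in wild-type mice.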

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

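The tests of the 3 patterns weighed here were chosen after the results were seen, as was the test of a difference between experiments, while the splits of the arrays and the differences between genotypes were set beforehand.

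The interferon-gamma-induced list had a median of -0.40 for ABA with LPS in wild-type mice, with 0 of 19 members past the threshold, and its camera call was lost with an estimated correlation (adjusted p = 0.874). In the experiment with both genotypes Xist differed between those groups. The difference of list means was -0.35 in the wild-type-only experiment, where all 12 arrays had high Xist (exact permutation p = 0.0286, the smallest that 70 arrangements can give). Sex as read from Xist cannot give that difference, but chance could. These arrays were part of the fit in which the list was picked, which favours a low value there, and this p is not adjusted for the choice. Leaving out any of the 12 arrays compared left between -0.45 and -0.29, which argues against a single array as the cause. Dilution by other cells stays open: the B cell and T cell list means differed by 0.48 and 0.18 in the wild-type-only experiment and by -0.53 and -0.29 in the other, and those of macrophages (-0.49 and 0.78), endothelium and stroma (-0.48 and 0.35) and megakaryocytes (-0.45 and 0.60) also moved as much, so a differing mix of cells is not excluded. The list means of natural killer and cytotoxic cells (-0.18 and -0.59) and of neutrophils (0.33 and 0.94) moved the same way in both experiments. So did pathway lists such as cell cycle genes (-0.35 and -0.34) and type I interferon genes (-0.22 and -0.32). Others, such as acute phase genes (-0.23 and 1.00), did not. A shared direction is thus not particular to the interferon-gamma-induced list. An effect of the diet stays an untested hypothesis.

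Erythroid genes had a median LPS change of -4.82 in wild-type and -0.51 in null mice of the experiment with both genotypes on the control diet, with a median difference of 4.03. Without null control diet no LPS replicate 1, whose erythroid list mean was low, the median difference was 2.37, and over all 8 left-out arrays it reached 5.84. A single array could thus account for part of the difference. The rest was not tested against the spread between arrays, and the list mean had an SD of 3.02 in null mice without LPS. A term for high Xist gave 4.48. It cannot decide on sex, because both wild-type arrays with LPS had high Xist and both without LPS had low Xist. Genotype stays open as an untested explanation with 2 arrays per group, as do sex and the handling of the spleens.

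The pancreas list mean differed by 1.64 between null and wild-type mice, with 0 of 15 members past the threshold and the camera call lost with an estimated correlation (adjusted p = 0.892). Without the arrays with high Cpa1 the difference was -0.021, as pancreatic tissue in some arrays would give, though those arrays were picked by a pancreas gene of the list itself. Cpa1 read 13.50 and 9.67 on those 2 null arrays and 9.11 and 6.19 on 2 wild-type arrays of the other experiment. In all, 2 of the 8 null arrays lay above every wild-type array of their experiment, which argues against genotype. Pancreas carried over at dissection is therefore a candidate source.

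For LPS in wild-type mice chance can be excluded: 1 of 90 splits of the arrays within experiments, the real one, gave as many genes on the control diet (2437, highest other 639) and 1 of 90 on the ABA diet (2054, highest other 308). For ABA with LPS in wild-type mice 3 of 100 drawn splits gave 2 or more genes, the real one included, with 2 in the highest other. Other splits reached the same 2 and only part of the splits was drawn, so chance is not taken as excluded for this count. Without LPS there are 18 splits, too few for a share under 0.05; 11 gave as many as the real 1, and the highest other gave 44, which points to a structure of the samples. For the interaction of diet and LPS the real count is 0, which all 100 drawn splits must reach (highest other 12), so the splits say nothing of chance. For genotype 47 of 100 drawn splits gave 1 or more, so chance cannot be excluded, and the highest other gave 1454, which points to a structure of the samples. For LPS by genotype the 18 splits are too few for a share under 0.05, with 42 genes in the real split and 32 in the highest other; 1 of the 18 gave as many as the real split.

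A sample stood apart from the other 3 of its group, relative to the range of the 4, 18 times among 214 sets of values, and chance marks about 1 in 20. For several, such as Epb42 on the ABA diet, Tek, and Fcer2a on the control diet, the 4 values differ only in the second decimal, so the mark reflects a spread near 0. With LPS on the ABA diet in the wild-type-only experiment, replicate 1 read 2.29 for Cd163 (others 2.48), 3.49 for Fcer2a (others 3.09 to 3.11), 8.60 for Ly75 (others 8.42 to 8.45) and 2.55 for Mgll (others 2.85 to 2.89). Replicate 2 read 2.68 for Btg2 (others 3.05 to 3.06), 2.29 for Epb42 (others 2.31) and 5.43 for Stard4 (others 4.71 to 4.83), and replicate 3 read 2.31 for Tek (others 2.30) and 4.91 for the adipose list mean (others 3.74 to 3.91). On the control diet with LPS, replicate 1 read 3.06 for Epb42 (others 2.31), 3.11 for Fcer2a (others 3.13), 2.99 for Kel (others 2.30), 2.59 for Tnf (others 2.30 to 2.35) and 6.01 for the cholesterol list mean (others 5.78 to 5.81). Replicate 2 read 5.69 for the pancreas list mean (others 2.38 to 2.41), replicate 3 read 12.66 for Gzma (others 11.95 to 12.07) and 6.07 for the natural killer list mean (others 5.56 to 5.61), and replicate 4 read 6.66 for the T cell list mean (others 7.07 to 7.14).

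Xist differed between the wild-type arrays compared in both contrasts between genotypes, so sex could enter their differences. Fewer genes passed there with a high-Xist term, chosen after seeing the data. Differences between genotypes passed their own test for the following named genes. For the ABA effect with LPS these were Bpifb1 (-3.03), Cpne8 (-1.23), H1f7 (-1.53), Il2ra (2.00), Klhl17 (-3.26), Pagr1a (-2.18), Slc35e1 (1.09), Smpdl3b (2.15), Sncb (-0.84), St14 (2.17), Tmtc2 (2.18) and Zswim1 (1.51). For the LPS effect on the control diet these were Adcy9 (2.84), Bpifb1 (4.19), H1f7 (2.91), Il2ra (-2.17), Klhl17 (3.15), Meg3 (3.07), Nup214 (-1.87), Pim2 (-2.23), Rab19 (-2.54), Tmtc2 (-1.75), Zbtb3 (4.15) and Zswim1 (-1.66). The fall of Il2ra on the ABA diet with LPS in wild-type mice was not seen in the wild-type-only experiment. With arrays centred on their medians, 0 genes passed for the ABA effect (limma, 992 at an unadjusted p under 0.05 before), and for the LPS effect Adcy9, Meg3, Nup214, Pim2, Tmtc2 and Zswim1 did not pass. Of these, Adcy9 and Meg3 then differed by 3.14 and 3.37 (limma, adjusted p = 0.0608 for both), more than before, and the others differed by less than before. Between the 2 experiments, effects in wild-type mice differed for 382 genes for LPS on the control diet, 242 for LPS on the ABA diet, 198 for ABA with LPS, 144 for ABA without LPS and 111 for the interaction. Genes whose probe set hardly varied in 1 of the experiments are among them, so these counts do not count differing responses alone. Sex could enter them too, as Xist was high on all arrays of the wild-type-only experiment. In the other it differed between the groups compared for LPS on the control diet and for ABA with LPS. It was also high on 1 of the 2 wild-type arrays without LPS on the ABA diet, so the remaining contrasts are not balanced for it either.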

How the results depend on the processing

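The high-Xist term, leaving out the 4 arrays with high Cpa1 and the erythroid list mean as a covariate were chosen after seeing the data, and the other alternatives were set beforehand. Of the named genes' values under alternatives, 4439 kept their side of the threshold, 834 kept the direction and no longer passed, 9 newly passed and 1 that had passed reversed. Among the 4439 are 891 that passed in neither setting, 81 of them with another sign, and the rest kept their direction. Of the list values, 401 kept both, 190 no longer passed and 6 reversed. Of the counts of genes, 136 stayed within 1.5 times and 126 did not. Unless a setting itself changes which arrays or genes are tested, the cause was not tested.

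The count for LPS in wild-type mice on the control diet (2437) stayed within 1.5 times with both scalings, both filters, the mean of probe sets, array weights, trended and robust variances, and all 10 arrays left out in turn. Setting a fold change over 1.5 as well and trended, robust variances moved none of the 11 counts by over 1.5 times.

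Quantile normalisation gave 1 gene for ABA with LPS (2 before) and 0 for ABA without LPS in wild-type mice and for genotype (1 each before; limma, 788 and 273 at an unadjusted p under 0.05 before). Centring arrays gave 0 for those last 2, 0 for ABA with LPS in null mice (13 before), 13 for ABA without LPS in null mice (24 before), 0 for diet by genotype (17 before) and 17 for LPS by genotype (42 before). With no filter genotype had 20, ABA with LPS in null mice 24 and diet by genotype 26. With the 60th percentile filter they had 0 each, ABA without LPS in null mice 11 and LPS by genotype 11. The mean of all probe sets gave 4 for ABA with LPS and 3 for ABA without LPS in wild-type mice, 1 for their interaction (0 before), 0 for genotype, 0 for ABA with LPS in null mice and 11 for diet by genotype.

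Array weights gave 1211 for LPS on the ABA diet (2054 before), 78 for ABA with LPS and 0 for ABA without LPS in wild-type mice, 0 for genotype, 111 and 6 for ABA in null mice with and without LPS, 214 for LPS in null mice (779 before), 77 for diet by genotype and 15 for LPS by genotype. A single fit of all 28 arrays gave 1 and 0 for ABA in wild-type mice with and without LPS, 12 for genotype, 189 and 159 for ABA in null mice, 1924 for LPS in null mice, 89 for diet by genotype and 261 for LPS by genotype.

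The wild-type-only experiment alone gave 13 genes for ABA with LPS, 62 without LPS and 37 for the interaction. The experiment with both genotypes alone gave 916 and 439 for LPS on the control and ABA diets, 31 for ABA with LPS, 0 without and 1 for the interaction. Without the experiment term there were 585 and 517 for LPS, 1 for ABA with LPS and 0 without.

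With the replicate number as a block, ABA in wild-type mice gave 0 with LPS and 0 without, genotype 0, ABA with LPS in null mice 5, diet by genotype 10 and LPS by genotype 26. The replicate numbers were not taken as a pairing of samples: residuals of arrays with the same number correlated at a mean of 0.0442 over 14 pairs (-0.155 to 0.380) in the wild-type-only experiment and -0.00487 over 56 pairs (-0.698 to 0.511) in the other.

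With the high-Xist term LPS on the control diet gave 1594 in wild-type and 485 in null mice, ABA with LPS 0 in wild-type and 0 in null mice, genotype 0, diet by genotype 2 and LPS by genotype 25. Without the 4 arrays with high Cpa1, ABA without LPS gave 2 in wild-type and 266 in null mice, the interaction in wild-type mice 1, genotype 100, LPS in null mice 1181, diet by genotype 28 and LPS by genotype 366. With the erythroid covariate LPS gave 1504 and 865 in wild-type mice on the 2 diets and 1783 in null mice, genotype 0, ABA with LPS in null mice 0, diet by genotype 11 and LPS by genotype 10.

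Leaving out each array in turn gave 1825 to 2415 for LPS in wild-type mice on the control diet and 1369 to 2272 on the ABA diet, 340 to 1323 in null mice, 2 to 3 for ABA with LPS and 0 to 6 without LPS in wild-type mice, 0 to 3 for their interaction, 0 to 67 for genotype, 13 to 177 and 41 to 355 for ABA in null mice with and without LPS, 7 to 129 for diet by genotype and 19 to 400 for LPS by genotype. Where this left a group with 1 array, that array was assumed to vary like the other groups.

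Col1a2, lower with LPS on the ABA diet, read 0.074 in the experiment with both genotypes alone. The cell cycle list turned to 0.42 for LPS on the control diet and to -0.89 for LPS by genotype with the erythroid covariate, which itself fell with LPS in wild-type mice. The cytokine list for ABA with LPS turned to 0.0059 in the experiment with both genotypes alone. Without the arrays with high Cpa1 the pancreas list turned to -0.025 for ABA without LPS in wild-type mice and to 0.00 for genotype, and the test of the erythroid list for genotype changed direction with the median at 0.11. Of the 86 list calls, 3 held with an estimated correlation. The lowest value is shared by 35.9% to 41.9% of the probe sets of an array, which limits what can be measured for genes of low signal.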

Other observations

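All tests in this part were chosen after the values were seen.

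Among the genes with the smallest p in a test of the difference between the 2 experiments are the following, whose probe sets hardly varied in 1 of them. For these the test does not show that the response to LPS differed, and the other genes were not looked at in this way. For S1pr5, a sphingosine-1-phosphate receptor of natural killer cells, LPS minus no LPS was -3.52 on the control diet in the wild-type-only experiment and -0.01 in the other, and -3.53 and 0.00 on the ABA diet (adjusted p = 1.86e-07 and 3.51e-07, limma). It read 6.39 ± 0.03 without LPS (SD, n = 2) and 2.88 ± 0.06 with LPS (SD, n = 4) on the control diet in the wild-type-only experiment, and at most 2.28 on the wild-type arrays of the other. For Rasd1, a glucocorticoid-induced Ras-like protein, the difference on the control diet was 0.00 in the wild-type-only experiment and 1.63 in the other, and for Wbp1 it was 0.00 and -2.60. Rasd1 and, on the control diet, Wbp1 lay at 2.29 on every array of the wild-type-only experiment. For Sergef the difference on the control diet was 0.00 in the wild-type-only experiment, where it read 3.14 to 3.15 on every array, and 0.85 in the other, and for Faf2 it was -0.03 and 1.04.

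Cell cycle and erythroid list means moved together within groups: their deviations from the group means over 28 arrays correlated at r = 0.92 (permutation within groups, p = 3e-05) and rho = 0.85 (p = 0.00014), and at r = 0.88 without the 2 arrays farthest from the median (permutation p = 0.00021). Within the experiments r was 0.96 (12 arrays, permutation p = 0.00082) and 0.90 (16 arrays, permutation p = 0.0316). The pair was chosen after its values were seen and its p-values are not adjusted for a choice among pairs of the 26 lists, and deviations within a pair of arrays mirror each other, so fewer than 28 are independent. The lower r, 0.90, is in line with the hypothesis that erythroid precursors carry the proliferation signal, and a shared cause of both lists would give it too.

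Ifng, on the 4 LPS arrays with high Xist in the experiment with both genotypes, read 3.06 log2 units above the 4 with low Xist. This missed the threshold (exact permutation p = 0.0571 over 70 arrangements), and diet and genotype are not balanced between those arrays, so sex and the groups cannot be told apart. Both wild-type control diet arrays are among the 4 with high Xist. In the wild-type-only experiment, where all arrays had high Xist, Ifng with LPS differed by -2.03 on the ABA diet without passing (exact permutation p = 0.2).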
